A study of Sus scrofa with 9 samples.

How the data were processed

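The samples were 9 cultures of the porcine ileal epithelial cell line IPI-2I, 3 uninfected, 3 taken at 2 h and 3 at 4 h after infection with Salmonella Typhimurium, each hybridised to 1 Affymetrix porcine array. Per the labels' protocols, biotinylated cRNA was made from 5 µg of total RNA. The deposited values are on the log2 scale, 1 value per probe set and array, made by the authors with RMA, a method that corrects background, normalizes between arrays and summarises probes, in R 2.7.0, per the submitters' processing notes. The annotation of probe sets came from the platform table, which can be old. Of 24123 probe sets, the 124 control probe sets were set aside and 23999 were tested. Of those, 10069 had 1 gene symbol, covering 6765 genes, 198 had several, and 13732 had none here. Through Entrez identifiers 9961 were found in a RefSeq gene table of assembly Sscrofa11.1, and 0 symbols changed. No genome coordinates were used here. No values were missing.

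Groups were taken from the infection and time labels. The tests, the gene lists, the rule for named genes and the alternatives, except where stated, were chosen before the data were examined. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust settings), over all 9 arrays with group as the only term. The comparisons were 2 h against uninfected, 4 h against uninfected and 4 h against 2 h, with Benjamini-Hochberg adjustment over the probe sets of each comparison and a threshold of 0.05. No filter on dim probe sets was applied. For genes, the probe set with the highest mean over all arrays stood for each symbol, probe sets with several symbols were left out, and the fit was repeated over 6765 genes. A log2 fold change is given with its moderated standard error.

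Gene lists fixed in advance, 21 with at least 5 measured genes, covered chemokines and cytokines, the NF-kB pathway, immediate early genes, interferon response, pattern recognition, antimicrobial defence, junctions, apoptosis, cholesterol and fatty acid synthesis, cell cycle, hypoxia and glycolysis, heat shock and unfolded protein response, oxidative stress, respiratory chain, intestinal epithelial markers, reference genes and ribosomal proteins. Markers of fibroblasts and muscle, leukocytes and endothelium were included because a culture could hold other cells, and 1 further list is not reported here. Each list was tested with limma's camera at a preset correlation of 0.01 against all other genes, with Benjamini-Hochberg adjustment over the lists of a comparison. The tests were repeated with the correlation estimated for each list and with fry, whose p tests for movement on balance one way and whose mixed p tests for change in either direction. Members were counted after adjustment over all genes and adjusted over the list alone.

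Named genes were, for each comparison with uninfected cells, the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap, and the 6 largest of each between 4 h and 2 h. To these came up to 4 members of each list past the threshold at 2 h or 4 h, or, where none passed, the 2 with the smallest p at either time. CXCL8, NFKBIA, CCL20, TNFAIP3, ICAM1, GAPDH, ACTB and HPRT1 were added as far as measured. Where no gene passed, the 10 with the smallest unadjusted p were named.

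The effects at 2 h and 4 h share their 3 uninfected arrays, so their agreement was set beside 100 simulations of unchanged groups with shared controls. So was the agreement without each array in turn, the latter chosen after the results were seen. For the share of called probe sets with the same sign, the simulated 4 h arrays kept the changes of the called probe sets. RNA quality was checked on the control probe sets for the 5 prime and 3 prime ends of 3 housekeeping transcripts. The 3 prime minus 5 prime difference changed by −0.01 at 2 h and +0.03 at 4 h against uninfected cells, and by +0.04 between the times (exact permutation p = 0.8, 0.7 and 0.7, two-sided). The 4 h arrays spread most, at 0.23, 0.47 and 0.44 for replicates 1 to 3, the lowest and the 2 highest of all arrays. The change at 4 h therefore ran from −0.01 without 4 h replicate 2 to 0.106 without 4 h replicate 1, and that between the times from −0.0042 to 0.117 without the same arrays. Between 4 h and 2 h the 2 control probe sets for 28S ribosomal RNA differed by +0.67 and +0.45 on the log2 scale (exact permutation p = 0.1 and 0.2), and the 2 for 18S by +0.97 and −0.48 (exact permutation p = 0.1 and 0.3). Limma called 0 of the 124 control probe sets at any comparison, with smallest adjusted p-values of 0.889, 0.417 and 0.327.

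The fit was tested on data simulated from these arrays, with 200 of 23999 probe sets changed and 10 simulations per comparison. For 2 h against uninfected, 85.7% of 1.5-fold, 98.8% of 2-fold and 100% of 4-fold changes were recovered, with 4.56% false among the calls. For 4 h against uninfected these shares were 86.3%, 98.7% and 100%, with 5.17% false, and for 4 h against 2 h they were 84.5%, 98.5% and 100%, with 5.55% false. The shares hold for 200 changed probe sets and an equal spread on all arrays. Where fewer probe sets change, the adjustment is stricter, so the shares do not give the recovery in the real comparison at 2 h. There CXCL2, at +0.80 on the log2 scale, was not called. For 4 h against uninfected, over 6765 genes, a list moved by 0.2 on the log2 scale was called in 10 of 10 simulations, and 0 of 200 other lists were. Errors were drawn independently for each gene, while the correlation estimated within lists of these data reached 0.36. The list simulations therefore do not show how often camera at its preset calls unmoved lists of correlated genes. The shift of 0.2 is also larger than the list medians given below.

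Alternatives were filters on dim probe sets (a log2 value of at least 5 on at least 3 arrays, or the brighter 50%), centring each array on its median, quantile normalization again, the replicate number as a block, only the 6 arrays compared, eBayes with trend and robust settings, array weights, a 2-fold minimum, an adjusted p under 0.01, 1 probe set per symbol, the mean of a gene's probe sets, and leaving out each array in turn. A result was counted as reversed only where it was called with the chosen setting or the alternative and changed sign. Cells infected with Salmonella Choleraesuis, which the series design also names, were not analysed here.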

Results

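Transcript levels were measured on 9 Affymetrix porcine arrays in IPI-2I cells, an epithelial cell line that originates from adult pig ileum. The arrays fell into 3 groups of 3: uninfected cells, and cells collected 2 h or 4 h after a 1 h exposure to Salmonella enterica serovar Typhimurium, a bacterium that enters gut epithelium. After the exposure, bacteria outside the cells were removed and the cultures stayed in gentamicin at 50 µg per ml, an antibiotic that does not enter cells. The uninfected cells carry an infection time of 0 h, so infection, time in culture and the antibiotic medium changed together in both comparisons with them. The labels call the cultures triplicates without saying whether they were grown on separate days. Titles of the uninfected samples have the letter b after the replicate number, unlike those of infected samples, and its meaning is not given in the sources used here. The p-values here measure only the spread between these samples. Array medians lay between 6.02 and 6.05 on the log2 scale, the correlation of any pair of arrays lay between 0.996 and 0.999, and the number of arrays limits the precision. The first principal component, with 28.4% of the variance, set the 4 h arrays apart, and the next one, with 21.4%, set uninfected replicate 1 apart from the other 8 arrays.

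At 2 h after infection no single gene passed the test, while chemokines and cytokines, the secreted proteins that attract and activate immune cells, were shifted upward as a group. Of 29 measured members, 21 had a positive log2 fold change, with a median of 0.07 (camera adjusted p = 0.000177; adjusted p = 0.308 with an estimated correlation). CXCL2, a chemokine that attracts neutrophils, stood at +0.80 ± 0.13 on the log2 scale (SE, 3 arrays per group), LIF, a cytokine of the interleukin 6 family, at +0.60 ± 0.13, and NFKBIA, the inhibitor that holds NF-kB in the cytoplasm, at +0.50 ± 0.12. None of these passed over all genes (adjusted p = 0.788 for each), and 3 members of the chemokine and cytokine list were higher when adjusted over the list alone. CXCL8, or interleukin 8, whose protein the submitters measured by ELISA, stood at +0.12 ± 0.28 (adjusted p = 0.929).

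Immediate early and AP-1 genes, which respond to stimuli without new protein synthesis, also lay higher as a group at 2 h, with 24 of 30 members positive and a median of 0.07 (camera adjusted p = 0.000336; adjusted p = 0.536 with an estimated correlation). Relative to the mean of the uninfected arrays, the list lay at −0.13, 0.02 and 0.11 on these arrays and at 0.11, 0.04 and 0.13 on the 2 h arrays, so the groups overlapped array by array. Without uninfected replicate 1, the lowest, the adjusted p was 0.0501. Genes of hypoxia and glycolysis had 29 of 36 members positive and a median of 0.05 (camera adjusted p = 0.00328; adjusted p = 0.343 with an estimated correlation), and without 2 h replicate 2 the adjusted p was 0.116. Here too the arrays overlapped, from −0.04 to 0.04 in uninfected cells and from 0.04 to 0.08 at 2 h. No member of either list passed over all genes, and 1 immediate early gene and 0 hypoxia genes were higher when adjusted over the list alone. The fry test, whose p asks whether the genes of a list move on balance one way, gave adjusted p-values of 0.165, 0.571 and 0.303 for the 3 lists, and its mixed p, which asks for change in either direction, passed for 0 of 21 lists at 2 h, against 16 of 21 at 4 h and 14 of 21 between 4 h and 2 h. Cholesterol synthesis, cell cycle, interferon, antimicrobial and respiratory chain lists had medians between −0.03 and 0.01 at 2 h, and none of the other 18 lists passed.

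Limma called 0 of 23999 probe sets at 2 h, with 1267 at an unadjusted p under 0.05 where chance gives 1199.95, and a smallest adjusted p of 0.851. By gene the count was also 0 of 6765, with 196 higher and 218 lower at an unadjusted p under 0.05. Every other setting tried, and every fit without 1 array, also called 0. For 8.82% of probe sets the groups did not overlap, against 10% by chance. The 10 genes with the smallest unadjusted p, none of which passed, were CXCL2, CYP2C32 (+0.35), SNAI1 (+0.39), LBP (+0.27), LOC100157433 (+0.27), LIF, ABRA (−0.29), TRIM55 (+0.31), TIE1 (+0.27) and NFKBIA.

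At 4 h after infection the largest rises were those of LIF, at +1.99 ± 0.13 (SE, 3 arrays per group; limma adjusted p = 0.000285), and VEGFA, the growth factor of blood vessels, at +1.46 ± 0.13 (adjusted p = 0.000995). CSF2, the granulocyte and macrophage colony stimulating factor, rose by 1.02 ± 0.13 (adjusted p = 0.00547). HMOX1, the enzyme that breaks down heme, rose by 0.86 ± 0.07 and the transcription factor MYC by 0.73 ± 0.06 (adjusted p = 0.000542 for both). INSIG1, which holds back the sterol sensing machinery in the endoplasmic reticulum, rose by 1.05 ± 0.14 (adjusted p = 0.00785). The largest fall was that of EGR1, an immediate early transcription factor, at −2.03 ± 0.39 (adjusted p = 0.0375), from uninfected arrays that ranged from 6.46 to 8.37.

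**Figure D1:**
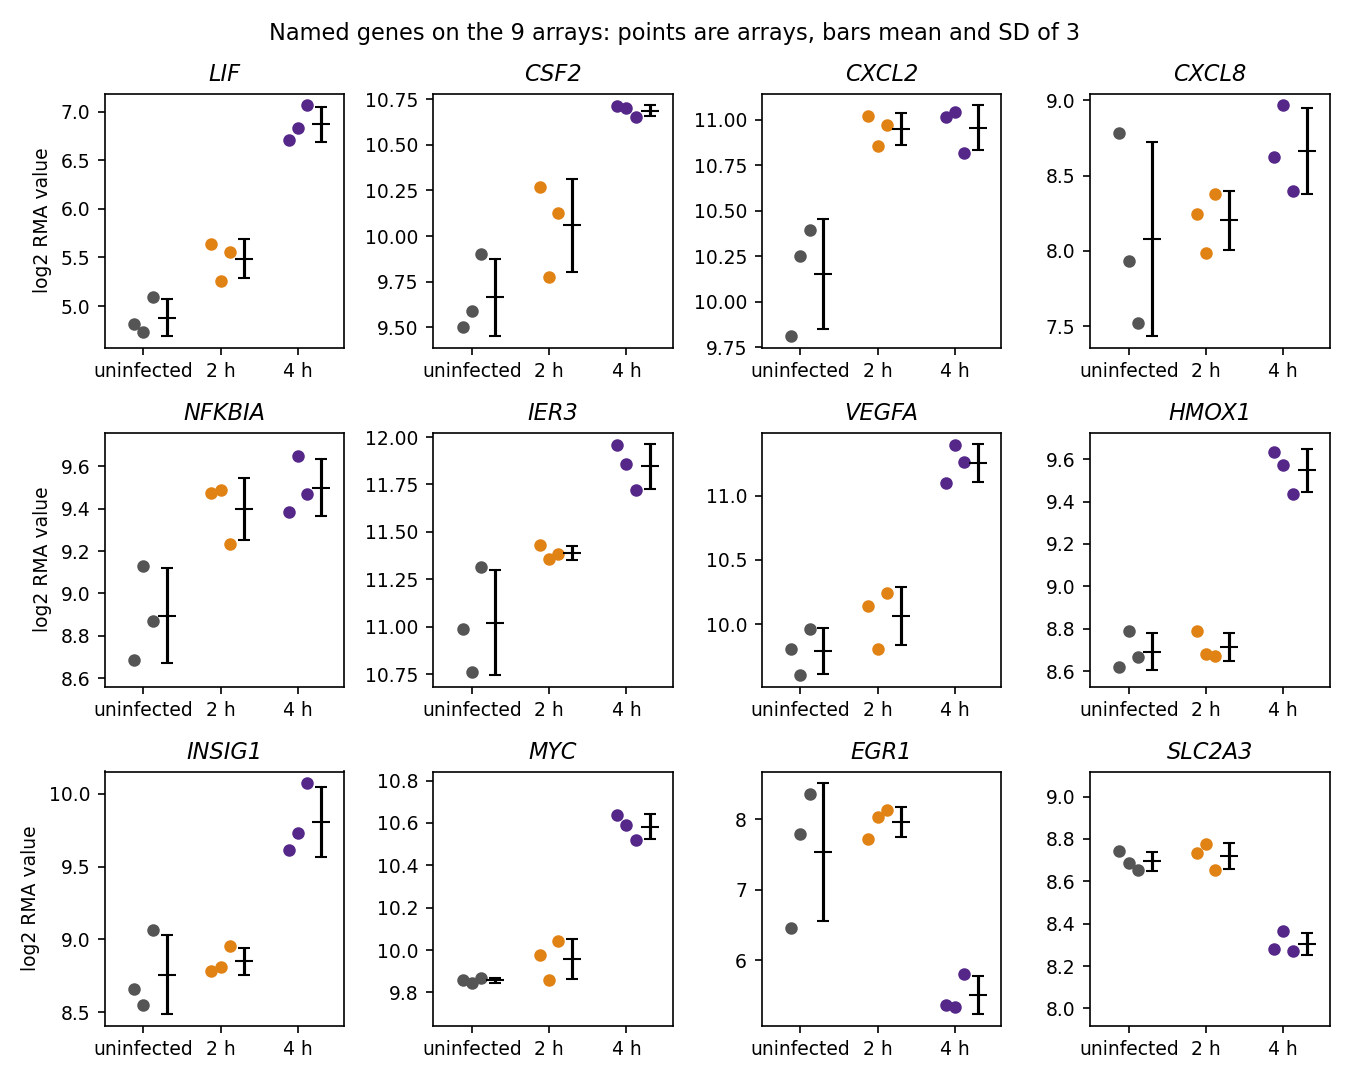
Deposited log2 values of 12 named genes on the 9 arrays, with 1 point per array and the mean and SD of 3 arrays beside each group. LIF went from a mean of 4.88 to 6.87 at 4 h and VEGFA from 9.79 to 11.25, while EGR1 had an SD of 0.98 among uninfected arrays and CXCL8 an SD of 0.65.

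Among chemokines and cytokines at 4 h, 3 of 29 measured genes rose and 0 fell over all genes, and 5 were higher and 1 lower when adjusted over the list alone. The risers were LIF, CSF2 and CXCL2, the last by 0.81 ± 0.13 (adjusted p = 0.0187; 0.0803 without 4 h replicate 2). The list as a whole was higher, with 22 members positive and a median of 0.07 (camera adjusted p = 0.00101; adjusted p = 0.447 with an estimated correlation; fry adjusted p = 0.0161). CXCL8 stood at +0.59 ± 0.28 and did not pass (adjusted p = 0.335), with uninfected values of 8.79, 7.93 and 7.52. Without uninfected replicate 1, the highest of these, its adjusted p was 0.0391, and over all alternatives for this gene it ran up to 0.571.

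Of 18 measured genes of the NF-kB pathway and its feedback, 3 rose at 4 h and 0 fell over all genes, with 4 higher and 2 lower when adjusted over the list alone. IER3, which limits NF-kB signalling and cell death, rose by 0.82 ± 0.12 (adjusted p = 0.0102), NFKBIA by 0.60 ± 0.12 (adjusted p = 0.0387; 0.127 without 4 h replicate 2; 0.0521 over all probe sets) and PLAU, the urokinase protease, by 0.69 ± 0.06 (adjusted p = 0.00133). As a list it was not called by camera, with a median of −0.01, a mean of 0.09 and an upward test direction (adjusted p = 0.536; fry adjusted p = 0.0331). The adhesion molecule ICAM1 stood at +0.03 ± 0.06 (adjusted p = 0.867). Probe sets for CCL20 and TNFAIP3 had no name here.

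Immediate early and AP-1 genes split at 4 h, with 4 of 30 higher and 2 lower over all genes, and 7 higher and 8 lower when adjusted over the list alone. The risers were MYC, ZFP36, a protein that directs cytokine mRNAs to decay, at +0.58 ± 0.09, the kinase PLK3 at +0.47 ± 0.08 and AREG, a ligand of the epidermal growth factor receptor, at +0.47 ± 0.08. The fallers were EGR1 and JUN, the AP-1 subunit, at −0.31 ± 0.06, and AREG and JUN are named after their values were seen. The list's median of 0.04, mean of −0.02 and upward test direction differed in sign (camera adjusted p = 0.469). EGR1 passed in 1 of the 9 fits without 1 array, and its largest adjusted p, without uninfected replicate 2, was 0.156.

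Cholesterol and fatty acid synthesis genes were higher as a list at 4 h, with a median of 0.10 over 28 genes (camera adjusted p = 0.00936; adjusted p = 0.956 with an estimated correlation). INSIG1 was the 1 member that rose, over all genes and also when adjusted over the list alone. The list's adjusted p was 0.177 without uninfected replicate 2 and 0.122 without 4 h replicate 3. Within hypoxia and glycolysis, VEGFA and HMOX1 rose and SLC2A3, a glucose transporter, fell by 0.39 ± 0.05 (adjusted p = 0.00723), also when adjusted over the list alone. Of VEGFA's 4 probe sets, the other 3 stood at +0.90, +0.04 and −0.01.

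Single members of other lists changed at 4 h. IRF1, a transcription factor of the interferon response, rose by 0.48 ± 0.08 and ELF3, a transcription factor of epithelial cells, by 0.57 ± 0.08. GPX1, a glutathione peroxidase, rose by 0.27 ± 0.05, and LBP, the lipopolysaccharide binding protein, by 0.27 ± 0.06 with an adjusted p of 0.0494. LBP passed in none of the 9 fits without 1 array (0.142 without 4 h replicate 2). Its probe set was dim, with a mean log2 value of 3.63, and the other LBP probe set stood at +0.06. PMAIP1, a promoter of apoptosis, fell by 0.49 ± 0.10. Adjusted over the list alone, the interferon list had 1 higher and 3 lower of 38, pattern recognition 1 higher of 19, apoptosis 1 lower of 30, oxidative stress 1 higher of 26, and intestinal epithelial markers 2 higher of 22.

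No member passed over all genes at 4 h in the lists of antimicrobial defence (28 measured), junctions (22), cell cycle (39), respiratory chain (47), ribosomal proteins (62), heat shock and unfolded protein response (45) and reference genes (13). Adjusted over the list alone, heat shock had 2 higher and 5 lower, reference genes 0 higher and 2 lower, and the remaining 5 of these had 0. Among the reference genes, GAPDH stood at −0.01 ± 0.04, ACTB at −0.06 ± 0.05 and HPRT1 at −0.03 ± 0.04, and TFRC, the transferrin receptor, at −0.79 ± 0.19 (adjusted p = 0.0738) and YWHAZ at −0.60 ± 0.17 (adjusted p = 0.121). Other members, named for the smallest p at either 2 h or 4 h, stood as follows at 4 h: XBP1 (−0.25), ATF4 (+0.25), SLC11A2 (−0.31), TFF3 (+0.22), OCLN (+0.15), CLDN6 (+0.09), CCNA2 (−0.27), TYMS (−0.17), SDHC (−0.15), NDUFA10 (−0.10), RPL37 (+0.51) and RPS24 (−0.10). Markers of fibroblasts and muscle (19 measured), leukocytes (16) and endothelium (12) had 0 genes passing over all genes, and 1 leukocyte marker was lower when adjusted over the list alone. Those with the smallest p at either time stood at 4 h as DES (+0.20), THY1 (+0.22), CD86 (−0.24), LCP1 (−0.38), VWF (+0.14) and TIE1 (+0.13). The other probe sets of LCP1 stood at −0.19, −0.05, −0.03 and −0.03.

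Outside the lists, KMT5B, a histone methyltransferase, rose by 1.06 ± 0.12 at 4 h, ANKRD10 by 0.99 ± 0.12, PHLDA2 by 0.83 ± 0.10 and CLK4, a kinase of splicing factors, by 0.81 ± 0.12. The other 4 probe sets of KMT5B stood at +0.96, +0.46, +0.04 and −0.01. The largest falls after EGR1 were those of LOC595122 (−0.80 ± 0.15), PPP1R3B, which targets a phosphatase to glycogen (−0.73 ± 0.09), and CCNG2, cyclin G2 (−0.67 ± 0.10). THNSL1 (−0.66), JARID2, a partner of the Polycomb repressive complex (−0.63), CCDC71 (−0.62), FPGT (−0.61), MAP10 (−0.57) and ATP8B1, a phospholipid flippase (−0.55), completed the 10. Adjusted p-values of these 13 genes ran from 0.0018 for FPGT to 0.0401 for THNSL1.

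In total 106 probe sets were higher and 70 lower at 4 h, of which 9 and 2 changed at least 2-fold, and the groups did not overlap for 15.2% of probe sets, against 10% by chance. Of the 176 called probe sets, 94 had no single gene symbol, so they are not described by gene here. By gene, 59 were higher and 54 lower. Some named genes that passed over genes did not pass when limma was adjusted over all probe sets. These were NFKBIA and THNSL1 (adjusted p = 0.0521 for both), PMAIP1 (0.0608), GPX1 (0.0613) and LBP (0.0918). Of 33 named genes that passed, 18 passed in every fit without 1 array. The other 15 missed it at least once, 13 of them without 4 h replicate 3 and 12 without uninfected replicate 2. Among these 15, CCNG2 passed in 8 of the 9 fits, CLK4 and MAP10 in 7, and CXCL2, IRF1, PLK3 and ZFP36 in 6. GPX1 passed in 3, LOC595122 and NFKBIA in 2, EGR1, PMAIP1 and THNSL1 in 1, and LBP in 0. The counts were 12 and 5 without uninfected replicate 2, 67 and 45 without uninfected replicate 3, 62 and 39, 74 and 45, and 59 and 34 without 2 h replicates 1, 2 and 3, and 17 and 14, and 20 and 4 without 4 h replicates 2 and 3. Other settings at this threshold gave from 18 and 9 with only the 6 arrays compared to 269 and 173 with array weights. The 2 control probe sets for 28S ribosomal RNA stood at +0.59 and +0.40 at 4 h on the log2 scale (exact permutation p = 0.1 and 0.2, two-sided), and the 2 for 18S at +0.87 and −0.63 (p = 0.1 and 0.3), where 3 against 3 arrays can give no p below 0.1.

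**Figure D2:**
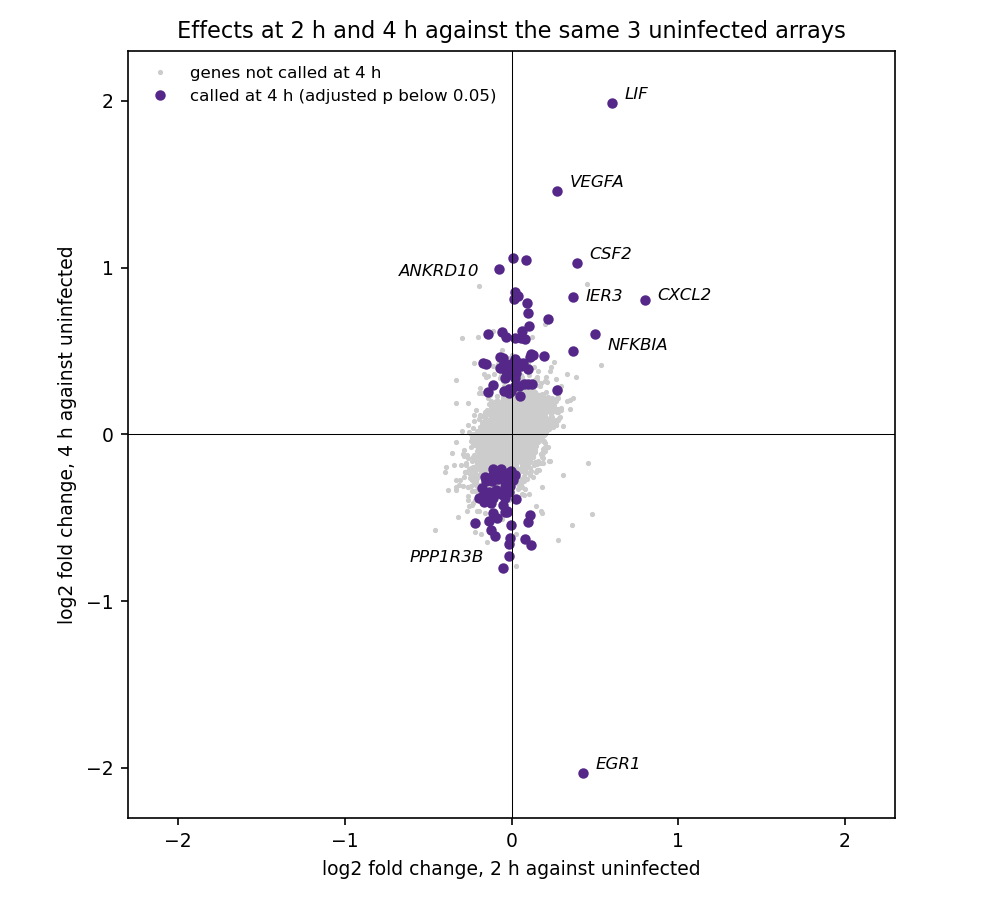
Log2 fold change of each gene against the same 3 uninfected arrays at 2 h (horizontal axis) and at 4 h (vertical axis), with 1 point per gene and the genes called at 4 h in purple. LIF lies at 0.60 and 1.99, CXCL2 at 0.80 and 0.81, and EGR1 at 0.43 and −2.03.

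From 2 h to 4 h after infection, LIF rose by a further 1.38 ± 0.13 (adjusted p = 0.00178), VEGFA by 1.19 ± 0.13 (adjusted p = 0.00359) and INSIG1 by 0.96 ± 0.14 (adjusted p = 0.0138; 0.0757 without 2 h replicate 2). HMOX1 rose by 0.84 ± 0.07 and MYC by 0.62 ± 0.06 (adjusted p = 0.00178 for both), after +0.02 and +0.10 at 2 h. CXCL2 and NFKBIA did not pass between the times, at +0.01 ± 0.13 and +0.10 ± 0.12 (adjusted p = 0.998 and 0.796), nor did CXCL8, at +0.46 ± 0.28 (adjusted p = 0.529). EGR1 fell by 2.46 ± 0.39 (adjusted p = 0.0181; 0.0861 without 2 h replicate 2), and PDE4B, a phosphodiesterase of cyclic AMP, fell by 0.96 ± 0.16 (adjusted p = 0.0225; 0.110 without 2 h replicate 2).

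Cholesterol and fatty acid synthesis genes were higher at 4 h than at 2 h, with 20 of 28 positive and a median of 0.10 (camera adjusted p = 0.0035; adjusted p = 0.885 with an estimated correlation). Of these, INSIG1 rose over all genes, and 5 were higher when adjusted over the list alone. Hypoxia and glycolysis genes were lower as a list, with 9 of 36 positive and a median of −0.07 (camera adjusted p = 0.0243; adjusted p = 0.630 with an estimated correlation), although VEGFA and HMOX1 rose within it and SLC2A3 fell by 0.41 ± 0.05. Adjusted over the list alone, 2 of its genes were higher and 4 lower, and the list's adjusted p was 0.224 without 2 h replicate 2, 0.0983 without 2 h replicate 3 and 0.134 without 4 h replicate 1. In the remaining lists PLAU, ZFP36, ELF3 and GPX1 rose, by 0.48, 0.55, 0.52 and 0.28, while PMAIP1 and XBP1, a transcription factor of the unfolded protein response, fell by 0.60 and 0.32. Of the 9 fits without 1 array, PLAU passed in 8, ELF3 in 6, ZFP36, GPX1 and XBP1 in 4, and PMAIP1 in 3. TIFA, an adaptor of NF-kB signalling named after its value was seen, fell by 0.34 ± 0.06 (adjusted p = 0.0282). None of the camera calls at any time held with an estimated correlation.

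**Figure D3:**
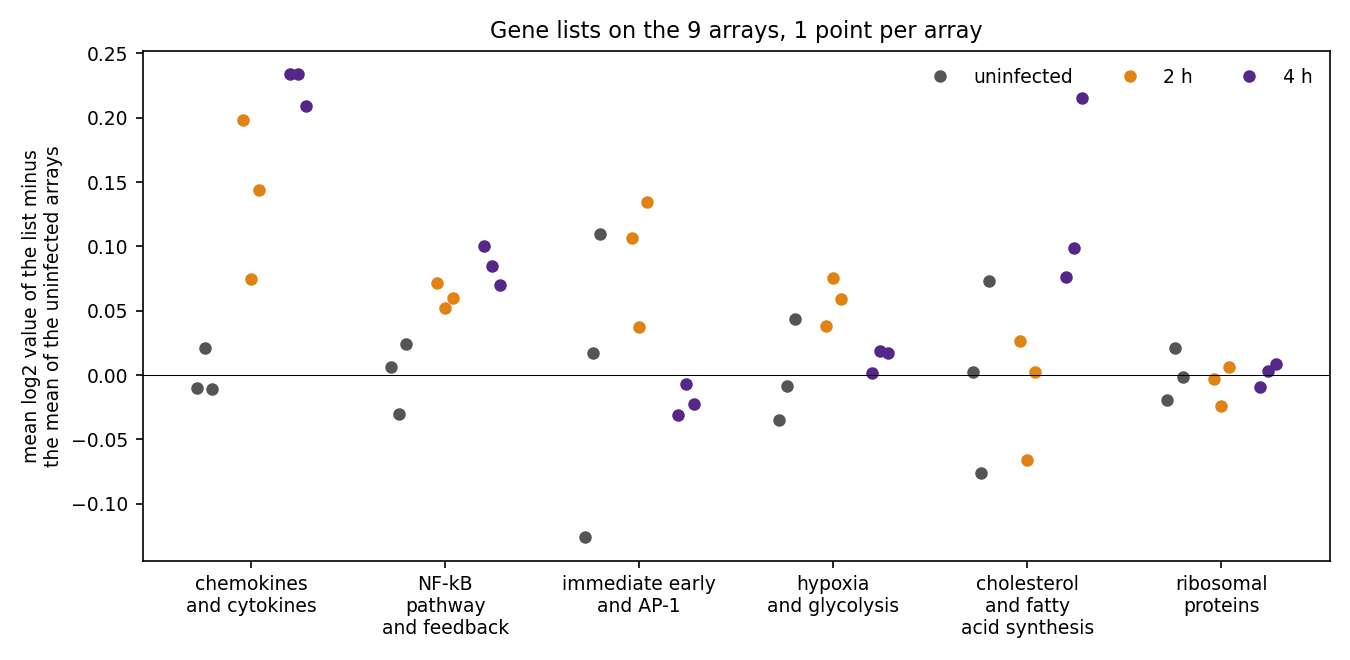
Mean log2 value of 6 gene lists on each of the 9 arrays, minus the mean of the uninfected arrays, with 1 point per array. Chemokines and cytokines lay from 0.07 to 0.20 at 2 h and from 0.21 to 0.23 at 4 h, against −0.01 to 0.02 in uninfected cells. The immediate early list lay from −0.13 to 0.11 in uninfected cells and from 0.04 to 0.13 at 2 h.

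The remaining large rises between the times were those of PMEPA1 (+1.09 ± 0.19, adjusted p = 0.0240; 0.109 without 2 h replicate 1), ANKRD10 (+1.07 ± 0.12) and KMT5B (+1.05 ± 0.12). The remaining large falls were CCNG2 (−0.78), PPP1R3B (−0.72), JARID2 (−0.71) and THNSL1 (−0.65). In total 166 probe sets were higher and 66 lower at 4 h than at 2 h, of which 12 and 3 changed at least 2-fold, and the groups did not overlap for 17.9% of probe sets, against 10% by chance. Of the 232 called probe sets, 143 had no single gene symbol. The largest rise of a called probe set was 1.62, and that probe set belonged to none of the named genes. The counts were 23 and 11, 32 and 13, and 51 and 14 without 2 h replicates 1, 2 and 3, 218 and 115, 32 and 21, and 30 and 10 without 4 h replicates 1, 2 and 3, and 240 and 100 without uninfected replicate 1. Of 27 named genes that passed, 12 passed in every fit without 1 array, and 14 were lost without 2 h replicate 2. The 15 that missed it at least once were ATP8B1, CCNG2, PLAU, INSIG1, ELF3, CLK4, GPX1, XBP1, ZFP36, EGR1, PDE4B, PMAIP1, PMEPA1, MAP10 and THNSL1. With limma adjusted over all probe sets, MAP10 and THNSL1 did not pass (adjusted p = 0.056 and 0.0516). Other settings gave up to 336 and 169, with array weights.

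Of the probe sets called at 4 h against uninfected cells, 83 higher and 39 lower were also called in that direction between 4 h and 2 h, and 0 in the opposite one. Independent lists of these sizes would share 0.733 and 0.193, but both comparisons use the same 4 h arrays. Of the 176 probe sets called at 4 h, 116 had the same sign at 2 h, or 65.9%. Simulations that shared the uninfected arrays gave 55.4%, with a range of 42.1% to 63.3%. For this share the simulated 4 h arrays kept the changes of the called probe sets, and no change was put in at 2 h. Across probe sets, which are not independent replicates, the log2 fold changes at 2 h and 4 h correlated at 0.335, with a covariance of 0.00478. Simulated unchanged groups gave 0.50 and 0.00387. Without uninfected replicate 3 the correlation was 0.527 against 0.601 in simulations with the same 8 arrays. The covariance was 0.0109 against 0.00548 and the share 83.9% against 56.2%. The share also lay above its simulated range without uninfected replicate 1, 2 h replicate 2 or 4 h replicate 2. It lay within that range without uninfected replicate 2 (76.5%, range 23.5% to 78.6%) or 2 h replicate 1 (62.4%, 41.4% to 67%). The same held without 2 h replicate 3 (60.2%, 39.5% to 65.5%), 4 h replicate 1 (60.6%, 44.7% to 65.1%) or 4 h replicate 3 (75%, 22.2% to 86.4%). The 3 uninfected arrays cannot be split into groups of at least 2, so part of any excess can come from them.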

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

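The tests on splits, ribosomal RNA as a covariate, change by signal level, the other EGR1 probe sets, EGR1 at 2 h and chemokine and NF-kB genes on uninfected replicate 1 were chosen only after the result was seen, as was the use made here of the fits without 1 array, while the other tests were planned.

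For 27 named genes the effect at 4 h differed from that at 2 h, tested in limma as the difference between the infected groups, at a threshold of 0.05. The difference was positive for 14. It was 1.38 on the log2 scale for LIF, 1.19 for VEGFA, 1.09 for PMEPA1, 1.07 for ANKRD10, 1.05 for KMT5B, 0.96 for INSIG1 and 0.84 for HMOX1. For CLK4 and PHLDA2 it was 0.79, for MYC 0.62, for ZFP36 0.55, for ELF3 0.52, for PLAU 0.48 and for GPX1 0.28. The difference was negative for 13. It was −2.46 for EGR1, −0.96 for PDE4B, −0.78 for CCNG2, −0.72 for PPP1R3B, −0.71 for JARID2, −0.65 for THNSL1, −0.62 for CCDC71, −0.60 for PMAIP1 and −0.55 for ATP8B1. For FPGT it was −0.51, for MAP10 −0.45, for SLC2A3 −0.41 and for XBP1 −0.32. As lists, cholesterol and fatty acid synthesis differed by a median of 0.10 and hypoxia and glycolysis by a median of −0.0706, both by camera and neither with an estimated correlation.

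Limma called 176 probe sets at 4 h and 0 at 2 h, where 1267 had an unadjusted p under 0.05. Without uninfected replicate 1, 0 were called at 2 h, with 922 at an unadjusted p under 0.05 and a smallest adjusted p of 0.446, while 231 were called at 4 h. This argues against that array alone holding the count at 2 h at 0. It does not bound the size of changes at 2 h, because the adjustment depends on how many probe sets change. CXCL2 was not called at 2 h, at +0.80, while it was called at 4 h, at +0.81. Changes at 2 h could also stay hidden because the fit without uninfected replicate 1 had fewer arrays. A difference in RNA quality stays open. With the 3 prime minus 5 prime difference as a covariate 149 were called at 4 h, 130 of them in both fits, but the 4 h arrays held both the lowest value of that difference, 0.23 on replicate 1, and the 2 highest, 0.47 and 0.44. Its change of +0.03 was 0.106 without 4 h replicate 1 and −0.01 without 4 h replicate 2. The 149 calls met the bound set before for speaking against this difference as the cause, but it covers only part of RNA quality. With any of the 4 control probe sets for 18S or 28S ribosomal RNA as a covariate, at most 4 were called at 4 h, and with the 1 for 5S ribosomal RNA 109 were. The median change of the 176 was 0.50 on the log2 scale without a covariate and from 0.45 to 0.51 with the 4 for 18S and 28S. Their median SE went from 0.08 to between 0.09 and 0.12. So the calls ended mainly because the errors grew, and their loss decides nothing about RNA quality. Between 4 h and 2 h the 232 calls went to 18, 0, 0 and 0 with these 4 and to 150 with 5S, with a median change of 0.52 before and from 0.45 to 0.50 with the 4, and a median SE of 0.08 before and from 0.09 to 0.14. A normalization that depended on signal level stays open too. The largest mean change of any of 10 equal groups of probe sets ranked by level was 0.0202, but RMA makes the arrays' distributions alike and holds such means near 0, so this value decides nothing. Also open is whether infection or the time in culture, the medium and gentamicin set the 4 h changes apart, as no uninfected array from 2 h or 4 h was used here.

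The 6 arrays of a comparison can be split into 3 and 3 in 10 ways, the real grouping included. At 2 h the real grouping called 0 and so did all 10. At 4 h it called 176 and for 4 h against 2 h 232, the highest other split called 0 in both, and so only 1 split, the real one, gave as many. These 10 splits are too few for a share under 0.05.

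EGR1 was 2.03 lower at 4 h than in uninfected cells (log2 fold change −2.03 ± 0.39), although its uninfected arrays spread from 6.46 to 8.37. A single faulty probe set is argued against by its other probe sets, at −1.86 ± 0.33 and −1.18 ± 0.43 (adjusted p = 0.0365 and 0.276). A single uninfected array with a high value is argued against as the whole cause, since the smallest fall without 1 uninfected array, replicate 3, was −1.62 (adjusted p = 0.0511). Over all alternatives for this gene the adjusted p ran from 0.00175 without uninfected replicate 1 to 0.156 without uninfected replicate 2. Time in culture and the change of medium may also lower EGR1, and they cannot be told apart from infection, because the value at 2 h, +0.43, followed the same steps and no uninfected array at 4 h was used here.

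CXCL8 passed at neither time, although the submitters measured its protein to check that the cells were activated. Its uninfected values were 8.79, 7.93 and 7.52, and without replicate 1, the highest, it stood at +0.94 ± 0.18 at 4 h (adjusted p = 0.0391, in a range of 0.0391 to 0.571 over all alternatives). That array was chosen for its high value, and leaving it out raises the difference whatever the reason for that value, so this decides nothing. Whether that array held an already activated culture stays open. The 6 chemokine and NF-kB genes that rose at 4 h had a median difference of −0.18 on it against the other uninfected arrays (SE 0.09, 0 of 6 higher), which lies within 2 SE of 0. These genes were picked for lying above an uninfected mean that includes replicate 1, which favours genes low on that array. The SE is over genes on 1 array, which are not replicates, so this value decides nothing. A first version of that test, on 28 other chemokines and cytokines, gave −0.09 (SE 0.06, 10 of 28 higher).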

How the results depend on the processing

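Every alternative in this part was planned, and of its tests only the simulations without 1 array were chosen after the result was seen. No called result changed its direction, and at 2 h 0 probe sets were called by limma under every alternative and without any single array. Where a value below is given without a reason, the cause was not tested. The filters leave fewer probe sets, the 6 array fit and the fits without 1 array use fewer arrays, and the stricter thresholds lower counts by themselves. Fewer arrays alone does not account for the counts, because some of these fits called more. Without uninfected replicate 1, 150 were higher and 81 lower at 4 h against uninfected cells. Why counts rose in such fits was not tested. Signal over background was not tested, and dim probe sets, which the filters leave out, add to the adjustment.

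Counts are given as higher and lower at 4 h against uninfected, then at 4 h against 2 h, beside 106 and 70, and 166 and 66. The filter on values of at least 5 gave 192 and 140, then 248 and 122, over 15309 probe sets, and the brighter 50% gave 233 and 181, then 294 and 149, over 11999. Only the 6 arrays compared gave 18 and 9 at 4 h, then 183 and 69. With trend and robust settings the counts were 213 and 143, then 269 and 126, and with array weights, of which uninfected replicate 1 had 0.412, they were 269 and 173, then 336 and 169. A 2-fold minimum left 9 and 2, then 12 and 3, and an adjusted p under 0.01 left 14 and 4, then 22 and 10. With 1 probe set per symbol there were 59 and 54, then 61 and 33. Median centring gave 98 and 65, then 181 and 52, and quantile normalization 137 and 67, then 186 and 62.

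Without 1 array, the higher count at 4 h ran from 12 (without uninfected replicate 2) to 150 (without uninfected replicate 1) and the lower from 4 (without 4 h replicate 3) to 81 (without uninfected replicate 1). Between 4 h and 2 h, they ran from 23 (without 2 h replicate 1) to 240 (without uninfected replicate 1), and from 10 (without 4 h replicate 3) to 115 (without 4 h replicate 1). Shared calls of both comparisons ran from 12 to 129 higher and from 4 to 53 lower, with the lowest without uninfected replicate 2 and 4 h replicate 3 and both highest without uninfected replicate 1, and were 167 and 88 in the brighter 50%. The correlation of effects was 0.243 in the brighter 50%, and without 1 array ran from 0.253 (without 4 h replicate 1) to 0.527, the covariance from 0.00403 (without 4 h replicate 1) to 0.0109, and the share with the same sign from 60.2% (without 2 h replicate 3) to 83.9%, all 3 highest without uninfected replicate 3. Unchanged groups simulated with the same arrays gave 0.447 and 0.601 for the correlation, and 0.00368 and 0.00548 for the covariance. For the share, simulations that kept the called changes at 4 h gave 54.4% and 56.2%. The share of 60.2% lay within its simulated range of 39.5% to 65.5%, and that of 83.9% above its range of 43.7% to 68.2%.

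With an estimated correlation 0 lists were called at any comparison. Adjusted p-values were then 0.308 for chemokines, 0.536 for immediate early genes and 0.343 for hypoxia at 2 h, 0.447 for chemokines and 0.956 for cholesterol at 4 h, and 0.885 for cholesterol and 0.630 for hypoxia between the times. Fry called 0 lists higher and 0 lower at 2 h, 2 higher and 1 lower at 4 h, and 0 higher and 1 lower between the times. Its adjusted p-values were 0.165, 0.571 and 0.303 for the 3 lists at 2 h, 0.459 for cholesterol, 0.0161 for chemokines (higher), 0.0331 for NF-kB (higher) and 0.0161 for reference genes (lower) at 4 h, and 0.372 for cholesterol, 0.231 for hypoxia and 0.00589 for reference genes (lower) between the times. With the mean of a gene's probe sets 2 lists were lower between the times, reference genes at 0.0411 among them, and with the filter fibroblast and muscle markers were higher at 2 h (adjusted p = 0.0158).

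Without 1 array, lists higher at 4 h numbered from 1 (without uninfected replicate 2, and also without 4 h replicate 3) to 2, lists lower from 0 to 1 (without uninfected replicate 1), and lists lower between the times from 0 (without 2 h replicate 3) to 2 (without 4 h replicate 2). Adjusted p-values ran as follows. Immediate early genes at 2 h ran from 4.77e-06 to 0.0501 (without uninfected replicate 1), hypoxia at 2 h from 0.000804 to 0.116 (without 2 h replicate 2), and cholesterol at 4 h from 0.00261 to 0.177 (without uninfected replicate 2). The respiratory chain at 4 h ran from 0.0251 (without uninfected replicate 1) to 0.837. Between the times, hypoxia ran from 0.00155 to 0.224 (without 2 h replicate 2), heat shock from 0.0407 (without 4 h replicate 2) to 0.576, and the respiratory chain from 0.0395 (without 2 h replicate 2) to 0.804.

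Replicate numbers were not taken to pair the arrays, although shared days are not excluded: deviations of arrays with the same number correlated between −0.09 and 0.218, over 0.1 in 3 of 9 pairs, and 5 of 9 arrays matched best to their own number. With the replicate block the counts were 90 and 68, then 140 and 82, and the shared calls 71 and 39. Of named genes called, the block kept 30 of 33 at 4 h and 25 of 27 between the times, the mean of probe sets 30 and 26, median centring 32 and 25, and trend and robust settings 32 and 27, and 0 reversed.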

Other observations

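The genes in this part were chosen after their values were seen, and the tests of both hypotheses were chosen after the result was seen.

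The genes below, outside the lists, passed at 4 h against uninfected cells in limma over all genes, and they were picked singly, without a test of any group. RYBP and EED, both parts of Polycomb complexes, rose by 0.43 ± 0.05 and 0.43 ± 0.08 (adjusted p = 0.00482 and 0.0387), and JARID2 fell by 0.63 ± 0.09. ESCO1, an acetyltransferase of cohesin, rose by 0.60 ± 0.09 (adjusted p = 0.0102), and OVOL1, a transcription factor of epithelial differentiation, by 0.79 ± 0.09 (adjusted p = 0.00482). CITED2, a coregulator of CBP and p300 that limits HIF-1 activity, fell by 0.53 ± 0.06 (adjusted p = 0.00439), and MEIS1, a homeobox factor, fell by 0.37 ± 0.05 (adjusted p = 0.00547). ARNTL, a transcription factor of the circadian clock, rose by 0.40 ± 0.05 (adjusted p = 0.00785) and BHLHE40, another, by 0.50 ± 0.10 (adjusted p = 0.0494).

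F3, the tissue factor that starts coagulation, rose by 0.33 ± 0.06 at 4 h (adjusted p = 0.0365), beside the urokinase gene PLAU, and STX11, a syntaxin of vesicle fusion, by 0.62 ± 0.09 (adjusted p = 0.00843). The receptors of lysophospholipids S1PR1 and LPAR6 fell by 0.29 ± 0.05 and 0.32 ± 0.05 (adjusted p = 0.0261 and 0.0181). RGS4, which shortens G protein signals, rose by 0.65 ± 0.11 (adjusted p = 0.0222), and LATS2, a kinase of the Hippo pathway, by 0.45 ± 0.07 (adjusted p = 0.0183).

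For 38 called probe sets at 4 h whose gene has others on the array, 49 of 61 other probe sets had the same sign (80.3%), with a median of 0.25 in that direction against 0.50 for the called ones. Between 4 h and 2 h this was 50 of 64 (78.1%) for 40 called probe sets.

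A hypothesis was that transcripts of splicing regulators rose together at 4 h, because CLK4, RBM39 and RBM23 rose, by 0.81, 0.26 and 0.29. Over 38 other splicing regulators the median was 0.00142, with 20 positive and 0 called (camera p = 0.553; p = 0.766 with an estimated correlation). Between 4 h and 2 h it was 0.03, with 22 positive and 1 called higher (camera p = 0.0727; p = 0.382 with an estimated correlation). A median near 0 over members that go both ways leaves the hypothesis open, and CLK3, another kinase of splicing factors, fell by 0.28.

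A further hypothesis was that ribosome biogenesis genes and other known targets of MYC followed the rise of MYC at 4 h. Over 36 of them the median at 4 h was −0.02 (−0.018 before rounding), with 17 positive and 0 called (camera p = 0.542; p = 0.880 with an estimated correlation). At 2 h the list lay lower, with 3 of 36 positive and a median of −0.09 (camera p = 1.1e-05; p = 0.299 with an estimated correlation). Between 4 h and 2 h it lay higher, with 27 of 36 positive and a median of 0.05 (camera p = 0.00493; p = 0.495 with an estimated correlation). The rise above uninfected cells at 4 h that the hypothesis predicts was not seen. The median lay within its SE of 0.02 from 0, so a small rise is not excluded and the hypothesis stays open. Neither the shift at 2 h nor that between the times holds with an estimated correlation.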
